A study of Homo sapiens with 24 samples.

How the data were processed

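HCT116, a human colon cancer cell line, was profiled on 24 one-colour Agilent expression arrays. Per the labels, cells were plated, and on the following day one dish was taken as the untreated starting point (time 0) while other dishes received DMSO, peptide-3 (Pep3) or the control peptide (Pep3M), each peptide at 10 µM. Dishes were collected after 24 or 48 h, and one further untreated dish after 24 h. This gives 8 groups with 3 arrays each. The labels speak of triplicates without saying whether these were separate cultures, so the replicates may be technical, and the number of arrays limits the precision. Per the labels, RNA was purified on columns and labelled with Cy3 by an Agilent kit for low RNA input.

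Per the file headers, the arrays (probe grid on build hg19) were read on an Agilent scanner with Feature Extraction 10.7.3.1 and protocol GE1_107_Sep09. The deposited processed signal and median spot and background signals are in intensity units. Per the file headers, the processed signal was background-subtracted and detrended within each array, with no normalization between arrays. The deposited spot quality columns hold other values, flags of 0 or 1 per spot. The series matrix deposited by the authors is on a log2 scale. Checked against the scanner files, each of its columns equals the log2 processed signal plus 1 constant per array (SD over probes of at most 0.0149, correlation of at least 0.999986), with no centring per gene. Its column medians ran from 9.47 to 9.67. How its 23173 probes were chosen is not stated; 99.98% of them were well above background on all arrays, and how the constants were derived stays unknown.

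Each array held 62976 spots, of which 4259 were controls. The 58717 gene spots carried 50599 probes, of which 28174 mapped through their RefSeq accession to a gene symbol. Gene spots marked by the scanner software as non-uniform or as population outliers, 283 to 613 per array, were left out, and 0 gene spots were saturated. Probe values were the log2 processed signal, averaged over replicate spots, minus the log2 75th percentile of that array. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 27734 probes. The brightest probe stood for a gene, which gave 22292 genes, 14102 of them with official symbols. No genome sequence was used, and positions on chromosomes are not given.

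Differential expression was tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes, 16 residual degrees of freedom) in R 4.3.3, with 1 model over the 8 groups. P values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as changed. All p values are two-sided, and intervals are 95% intervals from the model. Intervals and calls of single genes use the model without a block unless another setting is stated. The model with the replicate number as a block had 14 residual degrees of freedom. Same-numbered arrays share a slide, and correlations across genes between same-numbered arrays of the compared groups, each taken as its deviation from the group mean, all exceeded 0.1 in 13 of the 14 pairwise contrasts (0.183 to 0.755 in the 6 comparisons among Pep3, Pep3M and DMSO), so the numbers were taken as pairs and blocked counts are printed beside the unblocked ones. For Pep3 against Pep3M at 24 h the lowest same-numbered correlation, 0.183, lay below the highest between differently numbered arrays, 0.285. In the other comparisons among Pep3, Pep3M and DMSO every same-numbered correlation was the higher. Some contrasts against untreated cells at 0 h also overlapped, such as Pep3 at 48 h (0.122 and 0.32). Slides 1 and 2 were scanned on 1 day and slide 3 on another. Every group kept 1 position on all 3 slides, so slide position and group cannot be separated for a single contrast.

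The 31 gene lists were fixed before the data were examined, as were the contrasts, the tests and the rule for naming genes. Of 888 members written, 872 were on the array. Lists with at least 5 tested members were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01. Camera with a correlation estimated for each list, and fry, were run beside it (statmod 1.5.0 for the random block). The values printed for both come from the model without the replicate block, so they leave the shared slides out of account. Named genes were, in each of the 6 main comparisons among Pep3, Pep3M and DMSO, the 10 largest rises and the 10 largest falls among changed genes with official symbols whose 3 arrays of one group lay wholly above or below the other 3. In other contrasts the 5 largest each way were taken, and per list up to 4 members with the largest change, or with the smallest p where none changed. MDM2, MDM4, CDKN1A, BAX, BBC3, PMAIP1, FAS, GDF15, TP53INP1, SESN1 and TP53I3 were always named. A few genes that the rule named are not reported here. Of 107 changed gene and contrast pairs named in the main comparisons, 10 had another probe, and for 5 of these another probe had the opposite sign. Where one of the groups compared was not well above background on any of its 3 arrays, its values were raised to the lowest signal called well above background on the same array, and the difference is given as "at least" a fold. Where 1 or 2 of the 3 arrays of a group were above background, as for CFI and HTR3A, the fitted difference is given and rests partly on signals near background.

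Arrays were simulated by drawing values around each gene's mean with its own spread, without slide effects or correlation between genes. With known changes added to these, limma recovered 12.8%, 58.2% and 84.5% of genes shifted by 0.5, 1 and 2 log2 units for Pep3 against Pep3M at 24 h, with 3.2% of all calls false. For the interaction with time the recovered shares were 0.9%, 31.6% and 72.4%, with 3.6% of all calls false. A shift of 0.1 added to the p53 target list was called in 4 of 5 draws by camera, in 3 of 5 with an estimated correlation and in 5 of 5 by fry. These shares do not carry over to the real arrays, which share slides.

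Alternatives covered normexp background correction with an offset of 50 (on median signals, as the files hold no mean signal), quantile normalization, no filter on dim probes, a filter for probes well above background on all arrays, the mean of a gene's probes, the series matrix values, the replicate as a fixed block or the slide as a random block (consensus correlation 0.378), each contrast with its own groups alone, and leaving out each array. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.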

Results

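Gene expression was measured in HCT116 cells kept with the peptide Pep3, with the control peptide Pep3M, with the solvent DMSO or without treatment. The labels place the study's purpose in the interface between MDM4 and MDM2, the inhibitors of the tumour suppressor p53. Each of the 8 groups had 3 arrays, so n = 3 for every group value below, and values are log2 differences with 95% intervals. Between 52.8% and 66.32% of gene spots were well above background per array, the 75th percentile of the processed signal ran from 682 to 1861 intensity units, and the median spot coefficient of variation from 3.8% to 7.21%. Arrays of one group correlated at 0.980 to 0.995 across genes, genes not being independent replicates, and the median gene had a standard deviation of 0.193 to 0.267 within groups.

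A set of probes followed the position of an array on its slide. In Pep3M at 24 h and DMSO at 48 h, which share slide column 3, 104 probes lay over 0.7 log2 units beyond every other group, 46 of them higher and 58 lower. Of these, 96.15% sat on even spot rows in spot columns that are a multiple of 4, where 14.07% of all probes sit. In Pep3 and Pep3M at 48 h, which share slide column 4, 218 probes stood apart in this way, 100 higher and 118 lower, and 89.45% of them sat on even spot rows in spot columns 2 above a multiple of 4, where 14.17% of all probes sit. In untreated cells at 0 h and 24 h, which share slide column 1, 3 probes stood apart as higher and 90 as lower, and 1 and 70 of these sat at neither kind of position. Genes measured at either kind of position (6098 of 22292, 27.4%) are described below as measured at position-affected spots, whether or not their own value stood apart. Pep3 and Pep3M at 48 h share slide column 4, and Pep3 and DMSO at 24 h share column 2, where no probe stood apart. A shift equal in both groups of a column would cancel in these comparisons, and whether it was equal was not tested. Of their called genes 42.9% and 31.4% were measured at such spots.

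**Figure D1:**
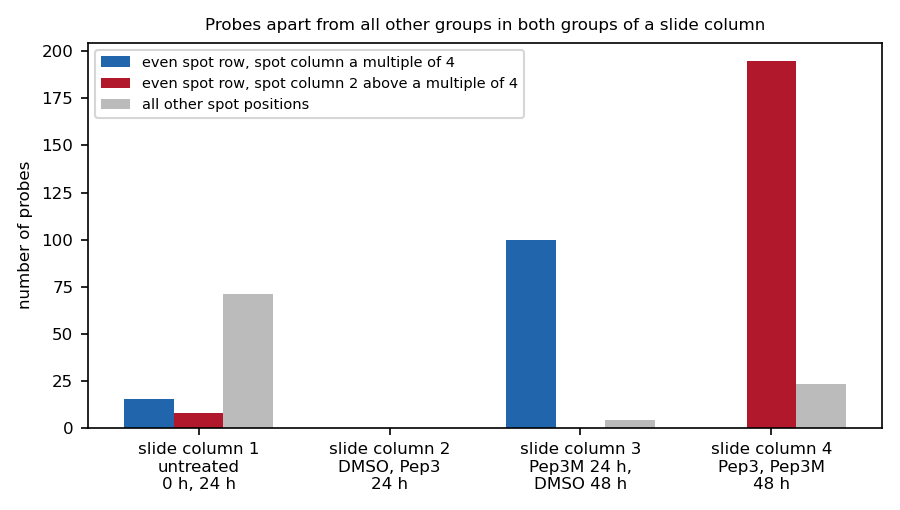
Number of probes (vertical axis) that lay more than 0.7 log2 units beyond every other group in both groups of a slide column (horizontal axis), coloured by the position of the spot on the array. Column 3 held 100 such probes on even rows in spot columns that are a multiple of 4, column 4 held 195 on even rows in spot columns 2 above one, and column 2 held none. Column 1, the untreated cells, held 3 higher and 90 lower probes, 1 and 70 of them at neither kind of position.

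To assess what Pep3 changed beyond the control peptide, both peptides were compared at 24 h. Genes of cholesterol synthesis rose together with Pep3. HMGCS1, the enzyme that makes HMG-CoA, rose by 1.37 (0.97 to 1.78), MVD, which makes isopentenyl diphosphate, by 1.35 (0.90 to 1.80), LSS, lanosterol synthase, by 1.33 (1.06 to 1.60), MSMO1, a methylsterol oxidase, by 1.22 (0.95 to 1.49) and FDFT1, squalene synthase, by 1.21 (0.93 to 1.5). SREBF2, a transcription factor that controls the pathway, rose by 0.69 (0.41 to 0.96). MSMO1 was measured at position-affected spots. Of the 25 tested members of the cholesterol list 17 rose and none fell, 25 lay above 0, and 21 passed when adjusted over the list alone. The list median was 0.78 (adjusted p = 8.24e-47, and adjusted p = 0.000211 with an estimated correlation), with 0.54, 0.94 and 0.78 within slides 1, 2 and 3.

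**Figure D2:**
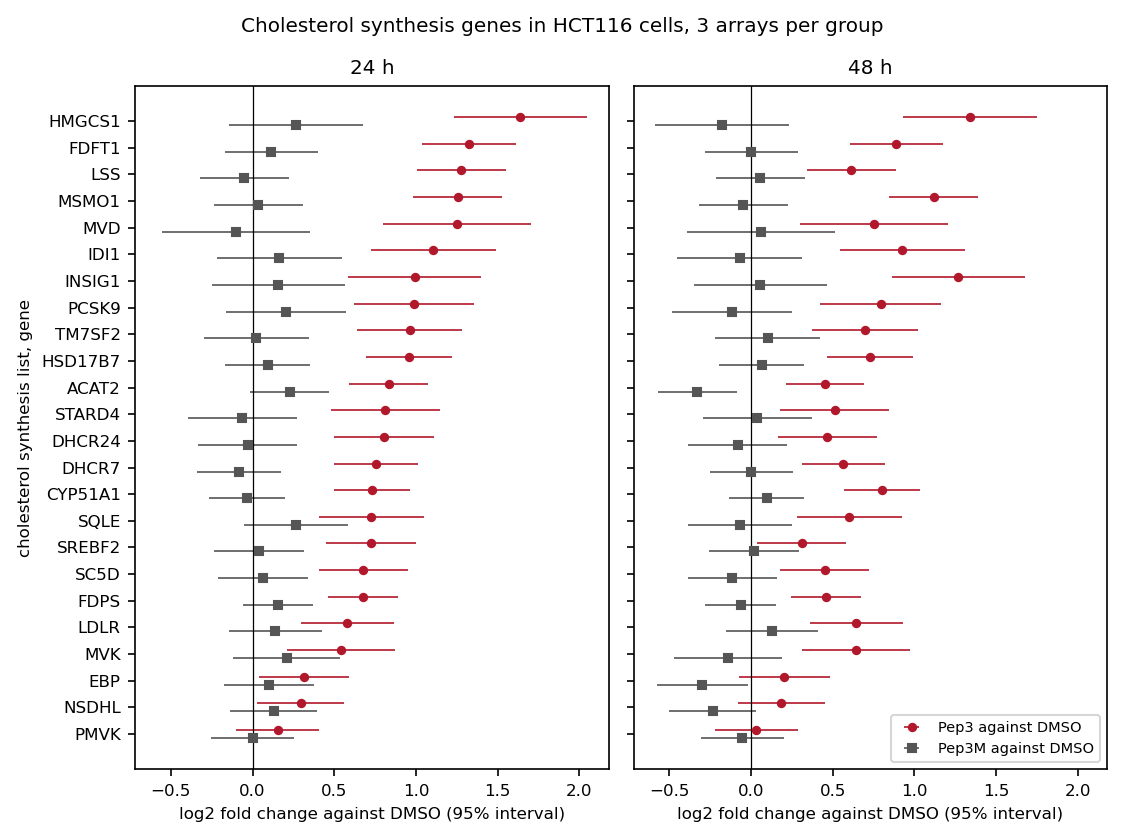
Log2 fold change against DMSO (horizontal axis) of 24 of the 25 genes of the cholesterol list (vertical axis) for Pep3 (red circles) and Pep3M (grey squares) at 24 h and 48 h, with 95% intervals from limma and 3 arrays per group. All 24 drawn lay above 0 with Pep3 at both times, with medians of the whole list of 0.81 and 0.64, while the Pep3M medians were 0.09 and -0.05.

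The fatty acid list lay higher with Pep3 at 24 h by its median, 0.46 over 14 genes (adjusted p = 1.09e-11, but adjusted p = 0.0592 with an estimated correlation, so the call was not kept). ACSS2, which makes acetyl-CoA from acetate, rose by 1.11 (0.77 to 1.44), FASN, fatty acid synthase, measured at position-affected spots, by 0.65 (0.35 to 0.95) and FADS1, a fatty acid desaturase, by 0.53 (0.30 to 0.75). Other genes that rose were FGFBP1, a carrier of fibroblast growth factors, by 1.33 (1.00 to 1.66), BIK, a pro-apoptotic BH3-only protein, by 1.05 (0.86 to 1.24) and ALDOC, a glycolytic aldolase, by 1.35 (0.77 to 1.92). ADM, the vasodilator adrenomedullin, fell by 0.60 (-0.86 to -0.34). Other named changes lay at position-affected spots. These were falls of AJM1 (at least 85.1-fold), RFX8 (-3.56), KRT85 (-2.72), RTN4RL1 (-2.66), GABRP (-1.73), HBM (-1.44) and SNORA5C (-1.07), and rises of GPR179 (at least 2.25-fold), TNS1 (1.72) and DLEU7 (1.30). Other probes of TNS1 and RTN4RL1, and 1 of 2 other probes of RFX8, had the opposite sign. CFAP65, GPR17 and GSDMA, at other spots, were at least 2.05-fold, 2.21-fold and 1.30-fold lower with Pep3, a bound in each case because one group did not rise above background. The calls of ADM, CFAP65, FADS1, FASN and GSDMA were lost under most alternatives.

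Across all genes at 24 h, limma called 99 of 22292 between the peptides, 57 higher and 42 lower with Pep3, and 62 of the 99 were measured at position-affected spots. With the replicate number as a block 1026 genes passed, 501 higher and 525 lower, including all 99. On the series matrix scale 75.2% of called genes were higher against 57.6% here. In 18.8% of genes the groups did not overlap, where chance gives 10%. That share holds for exchangeable arrays, here and in the other comparisons, and same-numbered arrays share a slide, which makes it a rough guide. Without the probes at position-affected spots 25 genes passed, and leaving out Pep3 replicate 3 or Pep3M replicate 1, 2 or 3 gave 47, 54, 50 and 57 genes.

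Camera called 15 of the 30 tested lists between the peptides at 24 h, 7 towards higher and 8 towards lower values with Pep3, and with an estimated correlation only the cholesterol list was kept. With the replicate block 14 lists were called, the NF-kappaB list being lost. Quantile normalization gave 13, without the G2 and mitosis, NF-kappaB, ribosomal protein, oxidative phosphorylation, proteasome and leukocyte lists and with the p53 target, p53 apoptosis, NRF2 and glycolysis lists added. G1/S and DNA replication genes had a median of -0.27 (adjusted p = 4.85e-08) and histone genes of -0.44 (adjusted p = 8.46e-08), both with an adjusted p = 0.541 with an estimated correlation. Histone medians within slides 1, 2 and 3 were 0.12, -0.69 and -0.78. Genes of G2 and mitosis lay at -0.18 (adjusted p = 0.000682), ribosomal proteins at -0.24 (0.000459), oxidative phosphorylation at -0.18 (0.0151) and the proteasome at -0.18 (0.00387), each with an adjusted p = 0.699 with an estimated correlation. Nucleolar ribosome biogenesis genes lay at -0.22 (adjusted p = 0.00032, or 0.541 with an estimated correlation), 8 of 31 passing when adjusted over the list alone. ATF4 targets of the integrated stress response lay at -0.24 (adjusted p = 0.000831, or 0.609 with an estimated correlation), which without position-affected spots became -0.10 (adjusted p = 0.0802). Interferon-stimulated genes lay at 0.20 (adjusted p = 0.000163) and NF-kappaB targets at 0.10 (0.0443), each with 0.541 with an estimated correlation. Immediate early genes lay at 0.08 (adjusted p = 0.0258, or 0.699 with an estimated correlation), and autophagy and lysosome genes at 0.06 (0.0402, or 0.606 with an estimated correlation). Leukocyte markers, of cells that a culture of this line should lack, lay at 0.16 (adjusted p = 0.0362, or 0.541 with an estimated correlation). Of those markers HLA-DRA, a class II antigen gene, had the smallest p at 0.75 (0.28 to 1.22, adjusted p = 0.179).

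At 48 h the cholesterol genes were again higher with Pep3 than with Pep3M. HMGCS1 rose by 1.52 (1.11 to 1.93), INSIG1, which retains the sterol sensor in the endoplasmic reticulum, by 1.21 (0.80 to 1.62), MSMO1 by 1.17 (0.89 to 1.44) and IDI1, isopentenyl diphosphate isomerase, by 1.00 (0.61 to 1.38). INSIG1 and MSMO1 were measured at position-affected spots. SREBF2, at 0.29 (0.015 to 0.564), and MVD and LSS, at 0.69 and 0.56, did not pass at 48 h. Of the 25 members 9 rose, 25 lay above 0 and 24 passed when adjusted over the list alone, with a median of 0.66 (adjusted p = 9.76e-75, or 1.09e-05 with an estimated correlation) and 0.67, 0.67 and 0.64 within the slides. FGFBP1 rose by 1.32 (0.99 to 1.65), BIK by 1.05 (0.86 to 1.25), TCN1, a vitamin B12 binding protein, by 0.94 (0.58 to 1.31) and the chemokine receptor CXCR4, at position-affected spots, by 0.93 (0.63 to 1.24). SPARCL1, also at such spots, was at least 2.45-fold higher. ANKRD2, a muscle ankyrin repeat protein, fell by 0.80 (-1.09 to -0.51). Most alternatives lost the calls of TCN1 and ANKRD2.

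ATF4 targets were lower with Pep3 than with Pep3M at 48 h as a list. The median was -0.44, 2 of 29 members lay above 0, and the adjusted p was 1.96e-26, or 0.0251 with an estimated correlation. Within slides 1, 2 and 3 it was -0.08, -0.74 and -0.52. No single member passed over all genes and 15 passed when adjusted over the list alone. STC2, a secreted glycoprotein, was at -0.71 (-1.01 to -0.41, adjusted p = 0.0711), DDIT3, the stress transcription factor CHOP, at -1.30 (-2.33 to -0.27) and CHAC1, which degrades glutathione, at -0.95 (-1.58 to -0.33).

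Limma called 21 genes between the peptides at 48 h, 20 higher and 1 lower with Pep3, 9 of them at position-affected spots, and 62 with the replicate block. Groups did not overlap in 9.1% of genes, where chance gives 10% only for arrays that share no slides. Without Pep3 replicate 1, Pep3 replicate 3 or Pep3M replicate 3 the count was 7, 13 and 11, and without position-affected spots 12. Camera called 10 lists, and with an estimated correlation the cholesterol and ATF4 lists were kept. The others were fatty acid genes (0.28, adjusted p = 1.21e-06, or 0.184 with an estimated correlation, with a median of 0.18 without Pep3M replicate 2), interferon-stimulated genes (0.19, adjusted p = 0.000148, or 0.535), NF-kappaB targets (0.20, adjusted p = 0.00107, or 0.0747), p53 targets and p53 apoptosis genes (given with the p53 genes), chaperones of the unfolded protein response (-0.18, adjusted p = 1.67e-06, or 0.306), G2 and mitosis (-0.10, adjusted p = 1.26e-05, or 0.717) and ribosome biogenesis (-0.08, adjusted p = 0.0122, or 0.757).

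Pep3 was next compared with its solvent. At 24 h HMGCS1 rose by 1.64 (1.23 to 2.05), LSS by 1.28 (1.01 to 1.55), MVD by 1.25 (0.80 to 1.70) and SREBF2 by 0.73 (0.45 to 1.00), and of the 25 cholesterol genes 19 rose and 25 lay above 0. The list median was 0.81 (adjusted p = 4.03e-69, or 1.83e-05 with an estimated correlation), within the slides 0.77, 0.98 and 0.81, and 24 members passed when adjusted over the list alone. Fatty acid genes had a median of 0.49 (adjusted p = 4.31e-15, or 0.023 with an estimated correlation), ACSS2 rising by 1.15 (0.82 to 1.48) and FADS1 by 0.62 (0.40 to 0.84). FGFBP1 rose by 1.33 (1.00 to 1.66), BIK by 0.90 (0.71 to 1.09), the endothelial lipase LIPG by 1.29 (0.87 to 1.71), FOXJ1, a regulator of motile cilia, by 1.62 (0.92 to 2.31), and the immediate early genes EGR1, at position-affected spots, and JUN by 1.26 (0.82 to 1.71) and 0.87 (0.52 to 1.22). ANKRD2 fell by 0.72 (-1.01 to -0.43). FDFT1 rose by 1.32 (1.04 to 1.61). DLEU7 (1.28) and MSMO1 (1.25) rose and GNG11 (-0.92) and KRTAP3-1 (-0.89) fell, all measured at position-affected spots. Most alternatives lost the calls of FOXJ1, ANKRD2 and KRTAP3-1.

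Limma called 51 genes between Pep3 and DMSO at 24 h, 47 higher and 4 lower, 16 of them at position-affected spots, and 177 with the replicate block. Groups did not overlap in 13.4% of genes, where chance gives 10%. Leaving out DMSO replicate 1, 2 or 3 or Pep3 replicate 3 gave 30, 21, 16 and 21 genes, and 33 passed without position-affected spots. Camera called 14 lists, of which the cholesterol and fatty acid lists were kept with an estimated correlation, and the G2 and mitosis list was lost with the replicate block and with quantile normalization. Histone genes had a median of -0.64 (adjusted p = 1.48e-20, or 0.138 with an estimated correlation), with 14 of 43 lower when adjusted over the list alone and slide medians of -0.11, -0.73 and -1.01. Interferon-stimulated genes lay at 0.29 (adjusted p = 6.96e-11) and immediate early genes at 0.16 (1.58e-09), both at 0.138 with an estimated correlation. G1/S genes lay at -0.18 (adjusted p = 1.2e-08) and ATF4 targets at -0.24 (2.26e-05), both at 0.323 with an estimated correlation. Ribosome biogenesis lay at -0.17 (adjusted p = 7.09e-06, or 0.301 with an estimated correlation), G2 and mitosis at -0.08 (0.04, or 0.836), autophagy and lysosome at 0.14 (0.000398, or 0.197) and NF-kappaB targets at 0.11 (0.0201, or 0.197). The remaining called lists hold p53 targets.

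At 48 h HMGCS1 was higher with Pep3 than with DMSO by 1.34 (0.93 to 1.75), INSIG1 by 1.27 (0.86 to 1.68), IDI1 by 0.93 (0.54 to 1.31) and BIK by 0.97 (0.78 to 1.17). The cholesterol list median was 0.64 (adjusted p = 7.44e-43, or 0.000357 with an estimated correlation) and within the slides 0.63, 0.65 and 0.68, with 14 of 25 members rising and 22 passing when adjusted over the list alone. SREBF2, at 0.31 (0.035 to 0.584), did not pass over all genes. CFI, complement factor I, rose by 1.57 (0.82 to 2.31), SPINK4, a goblet cell peptide, by 1.42 (0.78 to 2.06) and BIRC3, an inhibitor of apoptosis, by 0.64 (0.36 to 0.92). ATF4 itself fell by 0.87 (-1.27 to -0.47) and CDC20, an activator of the anaphase-promoting complex, by 0.59 (-0.88 to -0.30), both at position-affected spots. The other largest rises and all 10 largest falls lay at such spots. The rises were of EVX2 (5.80), AVP (3.96), GLTPD2 (3.27), TNFRSF4 (2.83), CALML5 (2.24), IL27 (1.89), CPEB1 (at least 1.78-fold) and OR4K14 (at least 1.73-fold). LRCOL1 also passed, but DMSO was above background on 1 of 3 arrays, slides gave 4.72, 3.95 and 0.44, and 7 of 15 alternatives lost the call. The falls were of AJM1 (at least 59.2-fold), KRT85 (-2.60), ANKMY1 (-2.44), RTN4RL1 (-2.34), HTR3A (-1.86), ZBTB16 (-1.58), H2AC8 (-1.55), ZNF577 (at least 2.75-fold), FERMT3 (at least 2.24-fold) and PEG3 (at least 1.44-fold). Most alternatives lost the calls of CFI, SPINK4, CDC20, HTR3A, ZBTB16, ZNF577, FERMT3 and PEG3.

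Limma called 214 genes between Pep3 and DMSO at 48 h, 114 higher and 100 lower, and 170 of these (79.4%) were measured at position-affected spots; 16 passed without such spots. With the replicate block 886 passed, and leaving out any 1 of Pep3 replicates 1, 2 and 3 or DMSO replicates 1, 2 and 3 gave 60, 142, 126, 62, 115 and 116. Groups did not overlap in 13.6% of genes, where chance gives 10%. Camera called 11 lists and only the cholesterol list was kept with an estimated correlation. ATF4 targets lay at -0.31 (adjusted p = 4.43e-12) and fatty acid genes at 0.28 (6.41e-07), both at 0.181 with an estimated correlation. Without Pep3 replicate 1 the fatty acid median was 0.19. NF-kappaB targets lay at 0.19 (adjusted p = 0.000949, or 0.0931 with an estimated correlation). Histones at -0.31 (adjusted p = 2.17e-07) and G2 and mitosis at -0.16 (2.17e-07) both had 0.645 with an estimated correlation. G1/S genes at -0.09 (adjusted p = 0.00119), interferon-stimulated genes at 0.14 (0.0225) and chaperones of the unfolded protein response at -0.13 (0.0105) all had 0.689 with an estimated correlation.

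Because the title of the series concerns p53, its regulators and standard targets were followed through the comparisons among Pep3, Pep3M and DMSO. None of the 11 reported passed the test over all genes in any of these comparisons without the replicate block. CDKN1A, which encodes the cell cycle inhibitor p21, was at 0.43 (-0.21 to 1.06) for Pep3 against Pep3M at 24 h and at 0.08 (-0.55 to 0.72) at 48 h, and at 0.44 (-0.20 to 1.07) and -0.02 (-0.65 to 0.62) against DMSO. MDM2, an inhibitor and target of p53, was at 0.18 (-0.12 to 0.48) and 0.42 (0.12 to 0.72, adjusted p = 0.802) against Pep3M. TP53INP1, a pro-apoptotic cofactor, came nearest, at 0.70 (0.36 to 1.04) for Pep3 against DMSO at 24 h with an adjusted p = 0.105, or 0.0499 with the replicate block. It was at 0.49 (0.14 to 0.83) at 48 h, and at 0.13 and 0.56 (0.21 to 0.90) against Pep3M. TP53I3, a quinone oxidoreductase, was at 0.47 (0.06 to 0.88) and 0.44 (0.03 to 0.85) against DMSO and at 0.41 (0.00 to 0.81) against Pep3M at 24 h, all unpassed without the block and at 0.00797, 0.00304 and 0.00899 with it. BBC3, the BH3-only protein PUMA, was at 0.59 (0.22 to 0.96, adjusted p = 0.334) for Pep3 and at 0.41 for Pep3M against DMSO at 24 h, and at 0.18 and 0.24 for Pep3 against Pep3M.

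**Figure D3:**
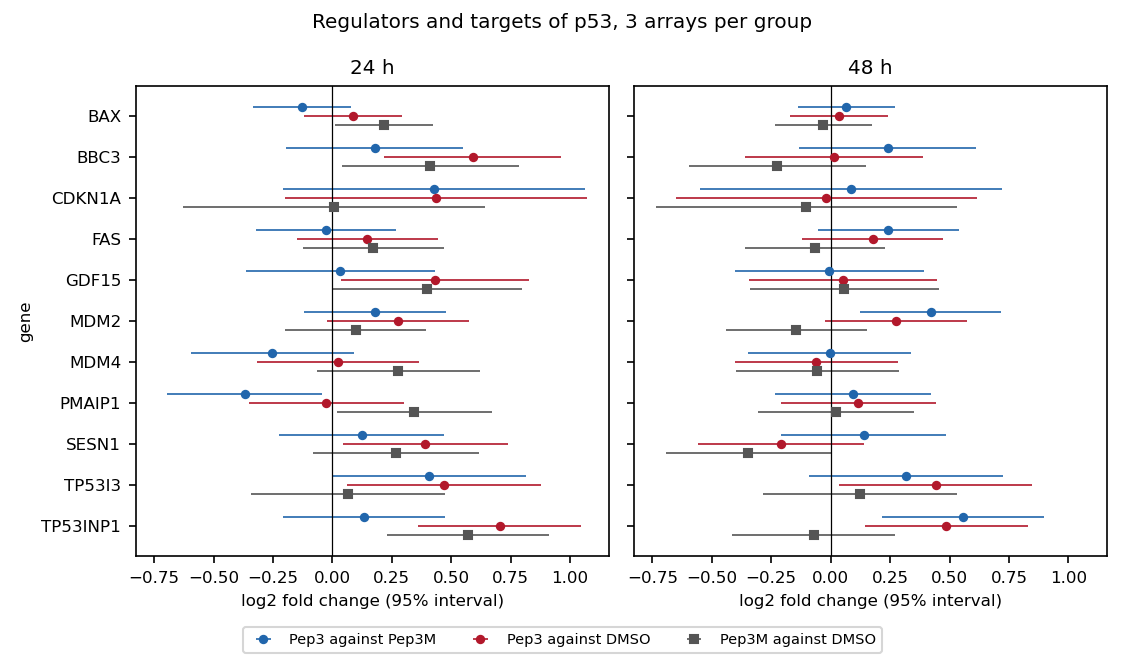
Log2 fold change (horizontal axis) of 11 genes (vertical axis) for Pep3 against Pep3M (blue), Pep3 against DMSO (red) and Pep3M against DMSO (grey) at 24 h and 48 h, with 95% intervals from limma and 3 arrays per group. CDKN1A lay at 0.43 and 0.08 for Pep3 against Pep3M, and no gene passed an adjusted p of 0.05 in this model without the replicate block. With the block in limma, TP53I3 passed for Pep3 against Pep3M at 24 h (adjusted p = 0.00899) and against DMSO at 24 h and 48 h (0.00797 and 0.00304). TP53INP1 then passed for Pep3 against DMSO at 24 h (0.0499).

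For Pep3 against Pep3M at 24 h and 48 h, MDM4 at -0.25 and -0.01, the pore former BAX at -0.13 and 0.07, the BH3-only protein PMAIP1 at -0.37 and 0.09, the death receptor FAS at -0.03 and 0.24, the cytokine GDF15 at 0.03 and -0.01 and the antioxidant SESN1 at 0.12 and 0.14. Against DMSO, Pep3 put MDM2 at 0.28 at both times, MDM4 at 0.02 and -0.06, BAX at 0.09 and 0.03, PMAIP1 at -0.03 and 0.11, FAS at 0.15 and 0.18, GDF15 at 0.43 and 0.05, and SESN1 at 0.39 and -0.21. Probes of CDKN1A, BAX, BBC3, FAS and SESN1 sat at position-affected spots. Other probes of MDM4 (3 of 3, Pep3 against DMSO at 24 h), BAX, MDM2 and TP53INP1 (Pep3M against DMSO at 24 h) had the opposite sign in some comparisons.

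As a list the 59 tested p53 targets shifted little. Their median for Pep3 against Pep3M was -0.01 at 24 h (mean 0.014, adjusted p = 0.266) and 0.09 at 48 h (adjusted p = 4.32e-05, or 0.325 with an estimated correlation), where 42 lay above 0 and slides gave 0.12, 0.07 and 0.19. Against DMSO it was 0.09 at 24 h (38 above 0, adjusted p = 4.72e-05, or 0.266 with an estimated correlation) and 0.11 at 48 h (46 above 0, adjusted p = 0.00408, or 0.645). All 3 calls were lost with the estimated correlation, in the model without the replicate block. GASK1B, a Golgi protein measured at position-affected spots, was the only changed member, at 0.91 against DMSO at 48 h, a call lost under most alternatives, and 1 member passed when adjusted over the list alone in each DMSO comparison. The p53 apoptosis list lay at 0.02 (adjusted p = 0.218) and 0.07 (0.00387, or 0.471 with an estimated correlation) against Pep3M and at 0.02 (0.00719, or 0.323) and 0.09 (0.0105, or 0.645) against DMSO, with BIK as its only changed member each time. The p53 arrest list lay at 0.06 at both times against Pep3M (adjusted p = 0.221 and 0.752) and at 0.22 (0.0049, or 0.323 with an estimated correlation) and 0.00 (0.57) against DMSO. Regulators of p53 lay at -0.10 (adjusted p = 0.84), 0.01 (0.678), 0.04 (0.21) and 0.02 (0.677) in the same order.

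The control peptide differed from DMSO mostly at position-affected spots. At 24 h limma called 14 genes, all 14 at such spots, among them rises of AJM1 (at least 133-fold), RTN4RL1 (2.80), KRT85 (2.72) and GABRP (1.71) and a fall of ZNF714 (-0.87), where other probes of RTN4RL1 and ZNF714 had the opposite sign and most alternatives lost their calls. No gene passed without such spots, but 8 did with the replicate block. Over all spots 797 of 22292 genes had an unadjusted limma p under 0.05 without the block, a share below 0.05. Chance alone would give 0.05 only for arrays that share no slides. At 48 h 50 genes passed, 35 higher and 15 lower, 43 of them at such spots. Without such spots 1 passed, or 33 with the replicate block. The rises were of EVX2 (5.39), AVP (3.51), GLTPD2 (2.93), TNFRSF4 (2.26), CALML5 (2.12), IL27 (1.72), CXCR3 (1.5), SALL3 (1.36), OR4K14 (at least 1.56-fold) and CPEB1 (at least 1.53-fold). The falls at such spots were of AJM1 (at least 46.4-fold), KRT85 (-2.67), CD86 (-1.88), GABRP (-1.30), SLC25A48 (-1.02), SNORA5C (-0.96) and CETN4P (at least 1.08-fold). The readthrough transcript ARHGAP27P1-BPTFP1-KPNA2P3 fell by 1.51 at other spots. Its call and those of AVP, OR4K14 and SLC25A48 were lost under most alternatives.

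The cholesterol list was not called between the control peptide and DMSO with all arrays, with medians of 0.09 (adjusted p = 0.124) and -0.05 (0.457). It was called higher with Pep3M at 24 h without Pep3M replicate 2 (0.13, adjusted p = 0.00742) and lower at 48 h without Pep3M replicate 1 (-0.08, 0.0156), where the adjusted p over all alternatives ran from 0.00742 to 0.938 and from 0.0156 to 0.997. HMGCS1 lay at 0.27 (-0.14 to 0.67) and -0.18 (-0.59 to 0.23). With the replicate block 164 and 495 genes passed between Pep3M and DMSO at 24 h and 48 h. At 24 h leaving out Pep3M replicate 1 or 2 or DMSO replicate 1 or 3 gave 6, 7, 7 and 5 genes. At 48 h leaving out DMSO replicate 1 or 3 or Pep3M replicate 2 or 3 gave 23, 28, 25 and 25, and with quantile normalization 57.5% of called genes were higher against 70.0% here. Groups did not overlap in 12.1% and 8.3% of genes, where chance gives 10% only for arrays that share no slides. Camera called 6 lists at 24 h and 1 at 48 h, and none was kept with an estimated correlation. At 24 h the replicate block gave 8 lists and quantile normalization 2, the immediate early and histone lists. At 24 h these were ribosomal proteins (0.29, adjusted p = 9.14e-12), immediate early genes (0.09, 0.00047), oxidative phosphorylation (0.14, 0.00047), the proteasome (0.15, 0.00148), p53 targets (0.11, 0.00493) and histones (-0.13, 0.00117), each with an adjusted p = 0.863 with an estimated correlation. At 48 h it was histones (-0.29, adjusted p = 6.72e-07, or 0.997 with an estimated correlation).

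Whether the effect of a compound changed with time was tested as an interaction. Between the peptides 5 genes passed, 4 higher and 1 lower at 48 h, 3 of them at position-affected spots, and AJM1, at such spots, was the only one with an official symbol. For Pep3 over DMSO 21 genes passed, 14 higher and 7 lower, 15 of them at such spots. Blocked counts were 104 and 288. For the 25 cholesterol genes the difference over DMSO between 48 h and 24 h had a median of -0.19 (adjusted p = 3.24e-05, or 0.911 with an estimated correlation).

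To describe the solvent, DMSO was compared with untreated cells at 24 h, where limma called 18 genes, 14 higher and 4 lower, but 687 without the filter on dim probes and 0 under normexp. BTBD16 rose by 0.90 (0.59 to 1.22), LEMD1 by 0.90 and RCAN2, a calcineurin regulator, by 1.28, the last pair at position-affected spots. MUC22, a mucin, fell by 4.57 and RNF223, at such spots, by 1.28; GSTA5, a glutathione transferase at such spots, was at least 1.05-fold higher, and BFSP2 rose by 1.32 near background. Without dim-probe filtering MUC22 was at 0.70, and under normexp GSTA5 and BFSP2 were at -0.01 and -0.23, so these 3 differences turned with the processing. Most alternatives lost the calls of BTBD16, LEMD1, RCAN2 and MUC22. The blocked count was 58, leaving out DMSO replicate 1, 2 or 3 gave 0, 8 and 5 genes, 1637 genes had an unadjusted limma p under 0.05, and 11.3% of genes did not overlap, where chance gives 10%. On the series matrix scale 88.2% of called genes were higher against 77.8% here. Camera called 13 lists and kept none with an estimated correlation. Among them were ribosome biogenesis (-0.24, adjusted p = 7.38e-09, or 0.487 with an estimated correlation), immediate early genes (-0.22, 4.74e-08, or 0.487), G1/S genes (-0.20, 1.06e-09, or 0.533), histones (0.34, 2.06e-07, or 0.533), heat shock genes (-0.13, 0.00521, or 0.533), glycolysis (-0.15, 0.00219, or 0.533) and cholesterol genes (0.07, 0.0418, or 0.616).

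In untreated cells 1585 genes changed over 24 h, 1155 higher and 430 lower, and 3870 did with the replicate block; leaving out untreated 0 h replicate 1, 2 or 3 or 24 h replicate 3 gave 838, 946, 2461 and 947. TMT1A, a methyltransferase, rose by 2.77 (2.21 to 3.33), TP53INP1 by 1.03 (0.68 to 1.37) and SESN1 by 0.63, while PMAIP1 fell by 0.59. MUC22 rose by 4.37, but was at -1.14 without the filter on dim probes. SLC46A2, at position-affected spots and with its call lost under most alternatives, PLA2G4D and FRMD4B were at least 2.21-fold, 1.61-fold and 2.09-fold higher. Actin ACTG2, IGFL2, TM4SF5 and the cytokine CXCL8 were at least 3.58-fold, 1.53-fold, 1.46-fold and 1.37-fold lower, and MIR181A1HG fell by 2.05. Of 59 p53 targets 9 rose and 2 fell (median 0.18, adjusted p = 0.00531, or 0.768 with an estimated correlation), and 13 passed when adjusted over the list alone. Of 25 cholesterol genes 10 rose (median 0.41, adjusted p = 2.49e-10, or 0.231 with an estimated correlation). Camera called 10 lists there and none was kept with an estimated correlation.

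Against the common starting point, limma called 5134 genes with Pep3, 4135 with Pep3M and 2912 with DMSO at 24 h, and 8418, 7749 and 7703 at 48 h. These contrasts share their control arrays, so their counts are not independent. With the replicate block the counts were 8277, 6800, 5234, 10911, 10538 and 10641, and without DMSO replicate 1 the DMSO count at 24 h was 1667. The median of all genes was -0.12 with Pep3 at 24 h and -0.12 with DMSO at 48 h and moved to -0.01 and 0.01 on the series matrix scale, where 64.9% of called genes were higher with Pep3 at 24 h against 54.2% here, 59.4% with Pep3M at 48 h against 47.3%, and 59.2% with DMSO at 48 h against 48.0%. TMT1A rose in all, by 4.70, 4.12 and 3.77 with Pep3, Pep3M and DMSO at 24 h and by 5.72, 5.13 and 5.24 at 48 h. TP53INP1 rose by 2.02, 1.89 and 1.32 at 24 h and by 2.68, 2.13 and 2.20 at 48 h, and BBC3, at position-affected spots, by 1.28, 1.10 and 0.69 and by 1.86, 1.62 and 1.85. TP53I3 rose by 1.17, 0.77 and 0.70 at 24 h and by 1.36, 1.04 and 0.92 at 48 h, and GDF15 by 0.91, 0.92 and 0.86 at 48 h. CDKN1A passed in none of them, at 0.36, -0.07 and -0.07 at 24 h and -0.06, -0.15 and -0.05 at 48 h. F3, the tissue factor of coagulation, at position-affected spots, fell by 2.78 with Pep3 and by 2.30 with DMSO at 24 h, and CPA4, a carboxypeptidase, by 2.62 and 1.92.

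Further largest changes against the starting point were mostly bounds. PRR15L, at position-affected spots, was at least 11.7-fold, 9.61-fold and 7.62-fold higher with Pep3, Pep3M and DMSO at 24 h and at least 28.0-fold, 18.0-fold and 19.7-fold higher at 48 h. GIMAP5 (at least 5.56-fold, Pep3 at 24 h), CCDC85A (at least 8.21-fold, Pep3 at 48 h), LRP1B (at least 11.3-fold, Pep3M at 48 h), PNMA2 (at least 5.94-fold, DMSO at 48 h) and TMEM266 (at least 4.80-fold, DMSO at 24 h) were higher, and PLA2G4D was at least 2.92-fold, 2.19-fold and 2.00-fold higher at 24 h. LEMD1 rose by 3.58 with Pep3 at 24 h and by 4.36 with Pep3M at 48 h, and GSTA5 was at least 7.10-fold higher with Pep3 at 48 h and 1.54-fold and 4.76-fold higher with DMSO, both genes at position-affected spots. IGFL2 was at least 1.72-fold, 2.10-fold and 2.69-fold lower at 24 h and 2.36-fold, 1.85-fold and 1.82-fold lower at 48 h. The linker histone H1-1 fell by 2.57 and 3.09 with Pep3 at 24 h and 48 h, and RNA18SN5, a ribosomal RNA, by 3.32, 3.00 and 3.03 at 48 h. ARRDC4, an arrestin family member, fell by 2.93 with Pep3M at 48 h, and KRT6A by 1.88 with DMSO at 24 h, as did EGR1 by 2.07. AJM1, EVX2, TUSC1, CAV3, LDHC, GPR179, CD86 and EID3 also ranked among the largest changes, all at position-affected spots.

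The remaining lists were not called between the peptides at 24 h with the main processing. For Pep3 against Pep3M at 24 h the medians were -0.03 for the apoptosis machinery (adjusted p = 0.84), -0.07 for chaperones of the unfolded protein response (0.405), -0.15 for heat shock genes (0.305), -0.06 for NRF2 targets (0.405), -0.15 for metallothioneins (0.423), -0.02 for hypoxia targets (0.428) and -0.04 for glycolysis (0.489). They were -0.11 for Wnt targets (adjusted p = 0.372), -0.21 for intestinal differentiation (0.405), 0.08 for mesenchymal genes (0.266) and 0.07 for endothelial and erythroid markers (0.428). Fibroblast markers had 2 tested members, too few for the test, with a median of -0.14. Between the peptides at 24 h, the median and the test differed in sign for p53 targets, the apoptosis machinery, NRF2 targets, hypoxia and glycolysis, and at 48 h the median and the mean or test did for metallothioneins, immediate early genes, the proteasome and mesenchymal genes. Against DMSO they did so for Pep3 at 24 h in unfolded protein chaperones, metallothioneins, oxidative phosphorylation, mesenchymal genes and endothelial and erythroid markers. The same held at 48 h for p53 arrest genes, p53 regulators, metallothioneins, glycolysis and oxidative phosphorylation, none of them called. Further changed members were MT1B, a metallothionein, at -0.95 and AKR1C3, an aldo-keto reductase whose call was lost under most alternatives, at 0.96, both for Pep3 against DMSO at 48 h and at position-affected spots.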

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

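The tests of spot position, and the test of slide position for the cholesterol genes, were chosen only after the result was seen.

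Each result here is an effect that differed between 24 h and 48 h when the difference itself was tested as an interaction. Between the peptides AJM1 differed by 8.55 (6.59 to 10.50), at a position-affected spot. In the same interaction 7 lists were called by camera, with medians that differed, G1/S genes by 0.25, histones by 0.42, ATF4 targets by -0.24, fatty acid genes by -0.19, immediate early genes by -0.21, ribosomal proteins by 0.29 and oxidative phosphorylation by 0.23, all with an adjusted p = 0.892 with an estimated correlation. For Pep3 over DMSO, AJM1 differed by -6.54, EVX2 by 6.35, GLTPD2 by 3.32, TNFRSF4 by 2.96, CALML5 by 2.45, CPEB1 by 2.34, IL27 by 2.33 and DLEU7 by -1.68, all at position-affected spots, and most alternatives lost the calls of CPEB1, DLEU7 and TNFRSF4. Lists that differed in that interaction were p53 arrest genes by -0.24, histones by 0.28, cholesterol genes by -0.19, fatty acid genes by -0.21, interferon-stimulated genes by -0.19 and immediate early genes by -0.23, all with an adjusted p = 0.911 with an estimated correlation.

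Probes stood apart in both groups of slide column 3 (Pep3M at 24 h and DMSO at 48 h) and in both groups of slide column 4 (Pep3 and Pep3M at 48 h), and each gene named above was measured at such a spot position. For genes of these probes that had another probe at other positions, the tables argue against an effect of treatment or time. Those other probes differed by a median of 0.069 in column 3 (23 genes) and 0.017 in column 4 (38 genes). The probes that stood apart differed by 1.54 and 1.45. The paired gap over genes, taken after the differences of the probes that stood apart were halved, had standard errors of 0.075 and 0.064. The genes named above had no other probe that passed the filter, so they were not among those tested. DLEU7 was higher by 1.28 with Pep3 than with DMSO at 24 h, both in column 2, where no probe stood apart. A fault tied to spot position is a candidate explanation, since 96.15% and 89.45% of the probes sat on 1 class of spot positions, a class found on the same arrays. What produced such a fault was not tested and stays open.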

How the results depend on the processing

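Leaving out the probes at position-affected spots, doing so with the replicate block, and using slides 1 and 2 or slides 1 and 3 alone were chosen after the results were seen, and all other settings before. The cholesterol list was called higher under each of the alternatives run for it, omissions of single arrays, fry and the estimated correlation included, with medians from 0.703 to 0.883 for Pep3 against Pep3M at 24 h and 0.567 to 0.719 at 48 h, and from 0.73 to 0.862 and 0.584 to 0.73 for Pep3 against DMSO. For genes near background only bounds on the fold are given, and the number of arrays limits how small a difference can be called. Where a group keeps 2 arrays, limma pools the spread over all groups. Counts given per setting are those that moved by over 1.5 times, and values of single genes are those that changed sign. Of these genes RTN4RL1, ZNF714, GSTA5, BFSP2 and MUC22 had passed the test, and the others had not. With slides left out or only the compared groups used, fewer samples enter the model. The all-bright filter and the omission of position-affected spots leave 18211 and 17085 genes to test. For the other settings the cause was not tested.

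Under normexp background correction 59 genes passed for Pep3 against Pep3M at 24 h, 33 and 122 for Pep3 against DMSO at 24 h and 48 h, 0 for DMSO against untreated cells, where limma gave 1637 genes at an unadjusted p under 0.05 with the main processing, 949 for untreated cells over 24 h, 1749 for DMSO at 24 h against the start, and 3 and 7 for the interactions between the peptides and over DMSO. FAS was then at 0.019 for Pep3 against Pep3M at 24 h, and MDM4 at 0.013 and PMAIP1 at -0.019 at 48 h. Against DMSO, MDM4 was at -0.027 and PMAIP1 at 0.008 at 24 h, and CDKN1A at 0.019 and BBC3 at -0.02 at 48 h. For DMSO against untreated cells GSTA5 was at -0.012 and BFSP2 at -0.229. Of 258 named values under this setting 192 kept direction and side, 57 no longer passed and 9 reversed.

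Quantile normalization gave 80 genes for Pep3M against DMSO at 48 h and 16 and 33 for the interactions, and put PMAIP1 at 0.003 for Pep3 against DMSO at 24 h; of 258 named values 243 kept direction and side. Without the filter on dim probes 85 and 135 genes passed for Pep3 against DMSO at 24 h and 48 h, 687 for DMSO against untreated cells and 79 for the interaction over DMSO; the median of all genes for DMSO against untreated cells was -0.107. MUC22 was then at 0.705 for DMSO against untreated cells and at -1.142 for untreated cells over 24 h. With probes well above background on all arrays 33 genes passed for Pep3M against DMSO at 48 h, 11 for DMSO against untreated cells, and 1 and 7 for the interactions, and all 177 named values it held were kept. The series matrix values gave 31 genes for Pep3M against DMSO at 48 h and 1 and 7 for the interactions, with FAS at 0.035 for Pep3 against Pep3M at 24 h and CDKN1A at -0.045 for Pep3M against DMSO at 24 h; 179 of 183 named values were kept.

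With the mean of a gene's probes BAX was at -0.03 for Pep3 against Pep3M at 48 h, MDM4 at -0.158 and BAX at -0.002 for Pep3 against DMSO at 24 h and 48 h, MDM2 at -0.121 for Pep3M against DMSO at 24 h, and MDM4 at 0.009 and BAX at 0.027 at 48 h; 245 of the named values kept direction and side, 7 no longer passed and 6 reversed.

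Without probes at position-affected spots 25 and 12 genes passed for Pep3 against Pep3M at 24 h and 48 h, 33 and 16 for Pep3 against DMSO, 0 and 1 for Pep3M against DMSO, where limma had given 797 genes at an unadjusted p under 0.05 at 24 h, and 2 and 5 for the interactions. That 797 is below a share of 0.05 of all genes, which chance alone would give only for arrays that share no slides. RTN4RL1 was then at 0.064 for Pep3 against Pep3M and at -0.201 for Pep3M against DMSO at 24 h, and ZNF714 at 0.225 in the latter. BAX was at -0.125 for Pep3 against Pep3M at 48 h, and BAX at -0.039 for Pep3 and 0.086 for Pep3M against DMSO. Adding the replicate block left these genes' values unchanged and gave 283, 44, 119, 106, 8 and 33 genes in the same 6 comparisons, 39 for DMSO against untreated cells and 2975 for untreated cells over 24 h.

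With the replicate block and all probes 1026, 62, 177, 886, 164 and 495 genes passed in the 6 comparisons, 58 for DMSO against untreated cells, 3870 for untreated cells over 24 h, 8277, 6800 and 5234 for Pep3, Pep3M and DMSO at 24 h against the start, and 104 and 288 for the interactions. With the slide as a random block these counts were, in the same order, 836, 64, 181, 710, 105 and 359, then 105 and 3543, then 7853, 6506 and 4979, then 58 and 145.

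On slides 1 and 2 alone 8, 2, 1, 17, 2 and 14 genes passed in the 6 comparisons, 0 for DMSO against untreated cells, 501 for untreated cells over 24 h, 2772, 2408 and 1311 for Pep3, Pep3M and DMSO at 24 h against the start, and 2 and 7 for the interactions. PMAIP1 was then at 0.112 for Pep3 against DMSO at 24 h and CDKN1A at 0.071 at 48 h. For Pep3M against DMSO, CDKN1A was at -0.036 at 24 h, and MDM4 at 0.061, BAX at 0.031 and FAS at 0.021 at 48 h. On slides 1 and 3 alone 3 genes passed for Pep3 against Pep3M at 48 h, 20 and 128 for Pep3 against DMSO, 0 for DMSO against untreated cells, 661 for untreated cells over 24 h, 1849 for DMSO at 24 h against the start and 0 for the interaction between the peptides, where limma on all slides gave 1919 genes at an unadjusted p under 0.05. For Pep3 against Pep3M, GDF15 was then at -0.072 and TP53INP1 at -0.104 at 24 h, and MDM4 at 0.087 and GDF15 at 0.195 at 48 h. MDM4 was at -0.019 for Pep3 against DMSO at 24 h, and for Pep3M against DMSO at 48 h BAX was at 0.012, PMAIP1 at -0.046 and GDF15 at -0.158.

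With only the groups compared in the model 2, 0, 4, 0, 0 and 3 genes passed in the 6 comparisons, where limma over all 8 groups gave 867, 1735 and 797 genes at an unadjusted p under 0.05 for the comparisons now at 0. Of these counts 867 and 797 are below a share of 0.05 of all genes, which chance alone would give only for arrays that share no slides. In the same setting 1 passed for DMSO against untreated cells, 6 for untreated cells over 24 h, 2134, 1456 and 664 for Pep3, Pep3M and DMSO at 24 h, 4783 and 4677 for Pep3M and DMSO at 48 h against the start, and 2 and 2 for the interactions. Of 258 named values there 129 kept direction and side, 129 no longer passed and 0 reversed.

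For the p53 target list the adjusted p ran from 0.0373 to 0.957 over the alternatives for Pep3 against Pep3M at 24 h, from 4.39e-07 to 0.325 at 48 h, from 6.07e-06 to 0.266 and from 7.15e-05 to 0.645 for Pep3 against DMSO, and from 0.000272 to 0.863 and 0.155 to 0.997 for Pep3M against DMSO. Quantile normalization gave 0.066 (adjusted p = 0.0384) for Pep3 against Pep3M at 24 h. For Pep3 against Pep3M at 48 h, Pep3 against DMSO at 24 h and 48 h and Pep3M against DMSO at 24 h, the medians of 0.093, 0.094, 0.108 and 0.106 had an adjusted p of 0.325, 0.266, 0.645 and 0.863 with the estimated correlation and of 0.199, 0.172, 0.306 and 0.683 with fry. Without the dim-probe filter the median was 0.101 (0.193) for Pep3 against DMSO at 24 h and 0.107 (0.257) for Pep3M against DMSO at 24 h, where normexp gave 0.105 (0.213), quantile normalization 0.078 (0.0748) and the mean of probes 0.094 (0.0596). For Pep3M against DMSO at 48 h it was 0.011 (0.939) on slides 1 and 2 and -0.002 (0.98) without position-affected spots and with the replicate block, the test pointing the other way in the latter. Camera called 57 lists over the 6 comparisons, and 6 were called with the estimated correlation and 8 by fry.

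Leaving out each array in turn moved the counts from 47 to 90 for Pep3 against Pep3M at 24 h and from 7 to 17 at 48 h, from 16 to 56 and from 60 to 142 for Pep3 against DMSO, from 5 to 17 and from 23 to 45 for Pep3M against DMSO, and from 0 to 19 for DMSO against untreated cells. They ran from 838 to 2461 for untreated cells over 24 h, from 1667 to 2874 for DMSO at 24 h against the start, and from 4 to 8 and from 8 to 17 for the interactions. Counts moved by over 1.5 times for Pep3 against Pep3M at 24 h without Pep3 replicate 3 (47) or Pep3M replicate 1 (54), 2 (50) or 3 (57), and at 48 h without Pep3 replicate 1 (7) or 3 (13) or Pep3M replicate 3 (11). They did so for Pep3 against DMSO at 24 h without Pep3 replicate 3 (21) or DMSO replicate 1 (30), 2 (21) or 3 (16), and at 48 h without Pep3 replicate 1 (60), 2 (142) or 3 (126) or DMSO replicate 1 (62), 2 (115) or 3 (116). For Pep3M against DMSO at 24 h the arrays were Pep3M replicate 1 (6) or 2 (7) and DMSO replicate 1 (7) or 3 (5), and at 48 h Pep3M replicate 2 (25) or 3 (25) and DMSO replicate 1 (23) or 3 (28). DMSO against untreated cells moved without DMSO replicate 1 (0 by limma, against 1637 at an unadjusted p under 0.05 with all arrays), 2 (8) or 3 (5), untreated cells over 24 h without 0 h replicate 1 (838), 2 (946) or 3 (2461) or 24 h replicate 3 (947), and DMSO at 24 h against the start without DMSO replicate 1 (1667). The interaction between the peptides moved without Pep3M 48 h replicate 3 (8), and that over DMSO without Pep3 48 h replicate 1 (10), Pep3 24 h replicate 1 (11) or 3 (12), DMSO 48 h replicate 1 (8) or DMSO 24 h replicate 1 (10), 2 (9) or 3 (11).

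The p53 target list median ran under these omissions from -0.05 to 0.038 for Pep3 against Pep3M at 24 h, from 0.06 to 0.156 for Pep3 against DMSO at 48 h, from 0.059 to 0.158 for Pep3M against DMSO at 24 h and from -0.05 to 0.033 at 48 h. It was called for Pep3 against Pep3M at 24 h without Pep3M replicate 1 (0.036, adjusted p = 0.0373), and no longer called for Pep3 against DMSO at 48 h without Pep3 replicate 1 (0.094, adjusted p = 0.12) or DMSO replicate 2 (0.06, adjusted p = 0.203), nor for Pep3M against DMSO at 24 h without Pep3M replicate 1 (0.076, adjusted p = 0.326) or DMSO replicate 2 (0.059, adjusted p = 0.256). At 48 h its test for Pep3M against DMSO pointed the other way without DMSO replicate 1 or 3 or Pep3M replicate 2. For Pep3 against Pep3M at 24 h FAS ran from -0.082 to 0.048, GDF15 from -0.03 to 0.066 and TP53INP1 from -0.035 to 0.276. At 48 h MDM4 ran from -0.07 to 0.068, CDKN1A from -0.188 to 0.31, BAX from -0.007 to 0.108 and GDF15 from -0.183 to 0.152. For Pep3 against DMSO at 24 h MDM4 ran from -0.116 to 0.131 and PMAIP1 from -0.117 to 0.074, and at 48 h MDM4 from -0.125 to 0.01, CDKN1A from -0.343 to 0.208, BAX from -0.039 to 0.096, BBC3 from -0.079 to 0.145 and GDF15 from -0.122 to 0.249. For Pep3M against DMSO at 24 h CDKN1A ran from -0.131 to 0.251 and TP53I3 from -0.093 to 0.175, and at 48 h MDM4 from -0.129 to 0.015, CDKN1A from -0.428 to 0.17, BAX from -0.105 to 0.03, PMAIP1 from -0.07 to 0.11 and GDF15 from -0.115 to 0.255.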

Other observations

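The test of slide position for the cholesterol genes, and the splits of the interactions that part every pair, were chosen only after the result was seen.

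Many interferon-stimulated genes were higher at 48 h than in untreated cells at the start, with DMSO and with Pep3, and neither list call was kept with an estimated correlation. Time and solvent are not separated, because untreated cells were measured only to 24 h. With DMSO at 48 h against the starting point IFIT2, an antiviral protein that binds RNA, rose by 3.15 (2.72 to 3.58), IFIT1, its relative at position-affected spots, by 3.03 (2.64 to 3.42), IFITM1, a block to viral entry at such spots, by 3.01 (2.53 to 3.49) and IRF9, a subunit of the interferon response factor, by 2.93 (2.40 to 3.47). Of 28 list members 20 rose and none fell with DMSO at 48 h (median 1.16, adjusted p = 1.22e-12, or 0.198 with an estimated correlation), and 20 rose with Pep3 (median 1.45, adjusted p = 6.41e-13, or 0.13 with an estimated correlation). Single genes that also changed with DMSO went both ways. COL1A1, a collagen chain, rose by 1.54 (1.18 to 1.91), FBLN1, fibulin, by 1.11 and the smooth muscle actin ACTA2 by 1.20, while TAGLN, transgelin at position-affected spots, fell by 1.85 (-2.40 to -1.30). GABARAPL1, an autophagy protein, rose by 1.51 (1.27 to 1.75).

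Growth and ribosome genes were lower at 48 h than at the start. In DMSO the G1/S genes had a median of -0.61 (38 of 50 falling, adjusted p = 1.07e-11, or 0.369 with an estimated correlation), among them POLA2, a subunit of DNA polymerase alpha, at -1.29 (-1.64 to -0.94), and CDC25A, a phosphatase that starts the cell cycle, at -1.01 (-1.29 to -0.74). G2 and mitosis genes lay at -0.48 (29 falling and 2 rising, adjusted p = 1.01e-05, or 0.511 with an estimated correlation), CENPF, a kinetochore protein, rising by 1.14. Ribosome biogenesis genes lay at -0.57 (22 of 31 falling, adjusted p = 6.39e-08, or 0.369 with an estimated correlation), with MRTO4 at -1.23 (-1.61 to -0.85) and PES1 at -1.15. Heat shock genes lay at -0.51 (10 of 18 falling, 1 rising, adjusted p = 0.00256, or 0.369 with an estimated correlation).

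Cholesterol genes were higher with Pep3 than with Pep3M or DMSO. An effect of slide row that is alike in both slide columns is argued against, because the 2 comparisons within a slide column hold Pep3 in opposite slide rows. The smaller of their list medians was 0.635 on its lowest slide. An effect particular to a single slide position cannot be told from group and stays open. Of growth states, only the change of untreated cells over 24 h was tested, and it is argued against. The 1143 other genes that changed there, those at position-affected spots left out, moved between the peptides by at most 0.105 of the proportion in which the list moved. The list kept its members at such spots. Their slopes were 0.033, 0.12 and 0.117 on slides 1, 2 and 3, and those of the list 0.99, 1.222 and 1.113. Other growth states stay open. G1/S and ribosome biogenesis lists were called lower with Pep3 at 24 h by camera, and neither was kept with an estimated correlation. A lower sterol level in Pep3 cells, under which targets of the sterol sensor LXR would fall, stays open. The median of 9 such targets was 0.061, 0.025 and 0.145 on slides 1, 2 and 3, and 6 of the 9 lay above 0. The rule fixed before counted a median above 0 on all slides against this explanation. A further demand, outside that rule, was that the median pass 2 standard errors of the members (0.088). The median over the slides, 0.061, did not. A biological effect of Pep3 on this pathway may underlie the rise, as a hypothesis found and tested on the same arrays.

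Outside the lipid lists 26 genes were higher with Pep3 than with DMSO at 24 h. An effect of slide row that is alike in both slide columns is argued against. Between the peptides at 48 h, where the rows are exchanged, the median of these genes was at least 0.256 on every slide. No other technical explanation was tested for these genes, and a biological one stays open.

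For each comparison of 3 arrays with 3 the 10 splits, of which only the real one was as large, are too few for a share under 0.05. In the order of the 6 main comparisons the real counts were 99, 21, 51, 214, 14 and 50 and the highest others 0, 1, 0, 0, 0 and 20. For DMSO against untreated cells they were 18 and 1, for untreated cells over 24 h 1585 and 11. Against the start the real counts were 5134, 4135 and 2912 for Pep3, Pep3M and DMSO at 24 h and 8418, 7749 and 7703 at 48 h, with highest others of 193, 0, 0, 0, 2 and 0. The 3 other splits that part every same-numbered pair of arrays gave 0 genes, or up to 1 for Pep3 against Pep3M at 48 h. For the interactions 100 splits were drawn, the real one included. Between the peptides 5 of them were as large as the real count of 5 (highest other 43). Over DMSO 3 were as large as the real 21 (highest other 41), a share under 0.05. These draws need not part same-numbered arrays, which share slides, so they do not exclude chance for either interaction. Of the 32 splits that part every same-numbered pair at both times, 2 were as large as the real count in each interaction, the real one included (share 0.0625). The other of these exchanges all arrays of one time and so measures the sum of both effects (97 and 183 genes), which says nothing about chance. The remaining splits gave at most 4 and 12 genes.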
